A study of Mus musculus with 9 samples.

How the data were processed

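Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 3 mouse pancreatic cancer cell lines for 3 histone marks, which gave 9 libraries. Per the labels, the lines were a female line and a male line without Kdm6a (female KO and male KO) and a male line with it (male WT), derived from pancreas of mice of mixed C57BL/6 and SV129 background and grown in F12/DMEM with EGF, with no treatment. Each combination of mark and line had 1 library. There was no replicate of any group and no female WT line, so no p-value was computed, and each comparison is between libraries, not between genotypes.

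Reads were processed with Bowtie 1.1.2 and SICER 1 on genome build mm9, per the submitters' processing notes. SICER joins neighbouring windows with more reads than background into enriched islands, called regions here. The authors' deposited lists, 1 per library, give the chromosome, start and end of each region and a whole number, used here as the count of reads in the region. The lists have no header, so that reading of the last column rests on its whole-number values and on the format that SICER writes. The control library, the false discovery rate and the total number of reads per library are not given in the sources used here. All region borders fell on a grid of 200 bp. The smallest gap between neighbouring regions was 400 bp for H3K4me3, 800 bp for H3K27me3 and 600 bp for H3K27ac in each of the 3 lists of the mark. No list was filtered, and all sequence names in the lists were chromosomes 1 to 19, X and Y.

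The reads in regions ranged from 2396174 to 18507923 per library. This sum is not the depth of a library, because it grows with the length that was called. Shares of regions are given with 95% Wilson intervals, which cover counting error only and treat regions as independent.

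Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with mm9 chromosome lengths from GenomeInfoDb 1.38.1. Lists were turned into masks of 200 bp bins. Pairs of lists were compared by the share of regions overlapped by at least 1 bp and by the Jaccard index, the length covered by both lists over the length covered by either. The level of chance placement came from 100 seeded circular shifts of the first list within chromosomes. Shared length was recomputed with bedtools 2.31.1 for 9 pairs, and 0 pairs differed. Regions of the 3 lists of a mark were also merged, and each merged region was given 1 of 7 patterns by the lists that overlap it. To allow for the WT list being shared by both KO comparisons, 1000 simulated draws spread the regions found in exactly 2 lists over the 3 pairs of lists, with odds taken from the numbers of regions found in 1 list alone. A region that differs by genotype enters those odds, so this draw is not a level free of genotype. A level for independent lists was computed beside it, from the 2 KO lists outside WT and with all merged regions as the total. That total holds WT regions, where the pattern cannot occur, which lowers the level. It also leaves out places that are in no list, which raises the level, so neither an excess nor a shortfall can be read from it. On simulated lists made from each WT list, 200 of 200 planted gains and 200 of 200 planted losses were recovered for each mark. Gains were placed where no list had a region and no reads were simulated, so this checks the arithmetic only.

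Reads per kb were compared over bins that all 3 lists of a mark hold, with the count of each region spread evenly over its length. H3K27ac regions within 12.5 kb were stitched into domains, and the 500 domains with the highest summed count were kept per library. Log2 ratios of reads in shared bins were taken in windows of 5 Mb with at least 20 kb of shared bins, minus the median over autosomal windows.

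The design, the tests and most alternatives were fixed before the data were examined. Regions are named by a rule fixed then: the 5 longest merged regions per mark in both KO lists and not WT, and in WT and neither KO, on autosomes or X, and the 5 longest domains of each kind. Coordinates are 1-based mm9 positions. The gene table used here belongs to another assembly (GRCm38.p6), so no gene was named from a coordinate, and comparisons at annotated promoters and of gene groups were not made. H3K4me3 regions took the place of promoters where the design allowed it.

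Alternatives were lists restricted to regions at or above their median count, regions closer than 1 kb merged, an overlap of 50%, lists of the same covered length taken from the highest count down, a margin of 5 kb, and other ways to stitch, rank and number domains. Chosen after seeing the data were lists scaled to the shallowest library of the mark (depth-scaled lists), the omission of chromosomes 4, X and Y, domains ranked by covered length, the scaling of the counts of named domains to WT, and domains from H3K27ac regions without H3K4me3. For a depth-scaled list, counts were multiplied by the ratio of reads per kb in shared bins, and a region was kept if it reached the smallest count the shallowest list has among regions at least as wide. Regions kept their full width, which greater depth can extend. The shallowest list stays whole by this rule, male KO for H3K4me3 and WT for H3K27me3 and H3K27ac, so only the other lists lose regions.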

Results

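Kdm6a, an X-linked gene, encodes a demethylase that removes methyl groups from lysine 27 of histone H3, and the series asked what its loss does to chromatin in pancreatic cancer cells. H3K27me3, the mark the enzyme removes, is found at silenced genes. H3K27ac marks active promoters and enhancers, and H3K4me3 marks promoters. Each mark was profiled in 3 cell lines from mouse pancreatic cancer, a female KO line, a male KO line and a male WT line, with 1 library each. The spread between replicates is therefore unknown, and no difference below has a replicate check. The female KO and male WT lines differ in sex as well as genotype. Reads in regions numbered 16144388, 7432359 and 12828427 for H3K4me3 in the female KO, male KO and WT libraries. For H3K27me3 they numbered 18507923, 4811961 and 2396174, and for H3K27ac 12295125, 11023981 and 3989395. The deletion of Kdm6a was not checked in these lists, since no gene was placed on mm9 here.

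H3K27me3 and H3K27ac regions covered more of the genome in both KO lines than in WT. H3K27me3 covered 345 Mb in the female KO line and 238 Mb in the male KO line, against 145 Mb in WT, which is 2.39 and 1.64 times the WT length. H3K27ac covered 201 and 147 Mb, against 110 Mb in WT. H3K4me3 covered 92.1 Mb in the female KO line, 69.3 Mb in the male KO line and 81.7 Mb in WT. The number of regions followed another order, with 21352, 28263 and 26288 H3K27me3 regions in the female KO, male KO and WT lists. The H3K27ac lists held 18501, 23965 and 20324 regions and the H3K4me3 lists 14056, 16908 and 15975. H3K27me3 regions had a median width of 8.4 kb in the female KO line, 5.2 kb in the male KO line and 3.8 kb in WT, and 351, 64 and 7 of them spanned at least 100 kb. The library with the most reads in regions also had the longest covered length for each mark. After scaling to the shallowest library, chosen after seeing the data, the female KO H3K27me3 list kept 6018 regions over 89.8 Mb, which is less than WT. The male KO list kept 26032 regions over 193 Mb. The scaled H3K27ac lists stayed longer than WT, at 155 Mb in the female KO line and 137 Mb in the male KO line, 1.40 and 1.24 times the WT length.

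**Figure D1:**
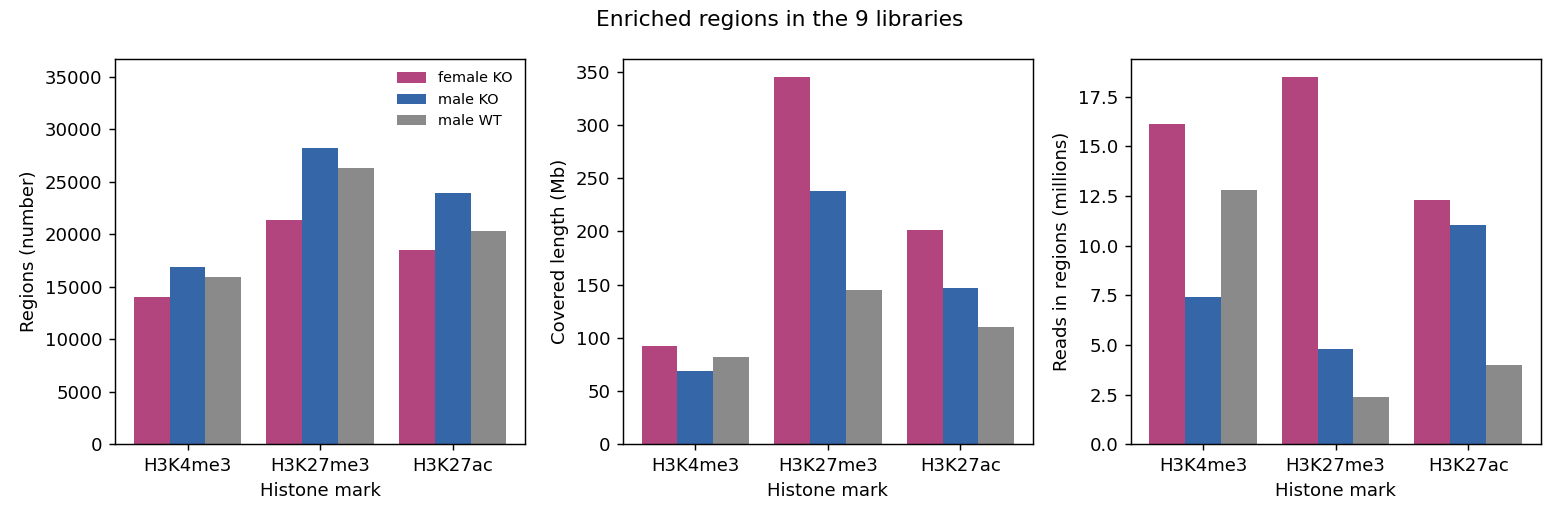
Number of enriched regions, covered length in Mb and reads in regions for the 3 marks, with 1 bar per library (female KO, male KO, male WT). For H3K27me3 the covered length falls from 345 Mb in the female KO line to 145 Mb in WT, while the reads in regions fall from 18507923 to 2396174.

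As deposited, the H3K4me3 lists overlapped more than those of the other marks in each pair of lines, by Jaccard index. Unequal covered lengths also limit the index, and the lengths were closest for H3K4me3. With lists of the same covered length, WT regions overlapped 64.2% of male KO regions for H3K4me3, 81.4% for H3K27me3 and 90.2% for H3K27ac. As deposited these were 84.5, 51.8 and 67.3%. The shortest list of a mark stays whole in that cut, male KO for H3K4me3 and WT for H3K27me3 and H3K27ac. These shares therefore depend on which list was cut and do not rank the marks. Between the 2 male lists as deposited, 84.5% of the male KO regions overlapped a WT region (84.0 to 85.0%) and 87.0% of the WT regions overlapped a male KO region (86.4 to 87.5%). The Jaccard index was 0.675, against a mean of 0.0157 for shifted lists. The female KO list had an index of 0.600 with male KO and 0.677 with WT. Of 18565 merged regions, 12061 were in all 3 lists, 594 in both KO lists and not WT, and 1563 in WT and neither KO. With lists of the same covered length the last 2 numbers were 80 and 61. A simulation that spreads the regions of exactly 2 lists over the 3 pairs placed 589 (541 to 639) in both KO lists and not WT. The odds of the simulation use the numbers in 1 list alone. A loss in both KO lines would lower the 589, so the simulation is not a level free of genotype. The level for independent lists was 195, but WT regions in its total lower it, so no excess over it can be read. The 2 male lists without the female KO list shared 1232 regions against 1102 (1042 to 1159) in the simulation, and female KO and WT without male KO 341 against 475 (431 to 518). Part of the number in both KO lists and not WT may come from the WT list, which both comparisons share. Among the 594 regions, 38.0% overlapped H3K27me3 in WT (34.2 to 42.0%), 40.7% in the male KO line (36.9 to 44.7%) and 50.5% in the female KO line (46.5 to 54.5%). H3K27ac was present at 37.0% of them in the female KO line and 38.7% in the male KO line, against 9.60% in WT. At the 1563 regions in WT and neither KO the order was reversed, with H3K27ac at 58.0% in the female KO line, 65.3% in the male KO line and 81.6% in WT. In both sets H3K27ac was thus more frequent in the lines whose H3K4me3 lists held the regions.

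The longest H3K4me3 region of both KO lists and not WT lay on chromosome 1, from 137737201 to 137754600, with 3030 reads in the female KO list and 308 in the male KO list. All 3 lines carried H3K27ac over its 17.4 kb. The other 4 were on chromosome 6 from 125088401 to 125104600, chromosome 19 from 43683601 to 43697000, chromosome 13 from 23588601 to 23601400 and chromosome 4 from 109645601 to 109657200. The region on chromosome 19 lay within H3K27me3 over its full 13.4 kb in all 3 lines. Of the 5 longest WT regions with no H3K4me3 in either KO list, the region on chromosome 5 from 115412401 to 115423800 held the most reads, 2293, which is 201 reads per kb. H3K27me3 covered 11.4 kb of it in the female KO line and 11.2 kb in the male KO line, and none in WT. H3K27ac covered all 11.4 kb in WT, 4.8 kb in the female KO line and none in the male KO line. The other 4, on chromosome 11 from 72278801 to 72293800, chromosome 8 from 3407201 to 3419400, chromosome 10 from 31310801 to 31321400 and chromosome 3 from 87312201 to 87321800, held between 469 and 584 reads in WT and carried H3K27ac in all 3 lines.

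H3K27me3 had the lowest Jaccard index of the 3 marks in each pair of deposited lists. The index cannot exceed the shorter covered length over the longer, and the lengths differed most for H3K27me3. This order may therefore come in part from list length. The male KO and WT lists shared 111 Mb, with a Jaccard index of 0.410 against 0.0414 for shifted lists. A WT region overlapped 51.8% of the male KO regions (51.2 to 52.4%), and a male KO region overlapped 75.2% of the WT regions (74.7 to 75.7%). The index was 0.456 between the KO lines and 0.319 between female KO and WT. Of 32532 merged regions, 7027 were in all 3 lists, 3157 in both KO lists and not WT, and 4002 in WT and neither KO. The regions in both KO lists and not WT covered 47.4 Mb and those of WT alone 11.7 Mb. With lists of the same covered length 92 regions were in both KO lists and not WT and 12555 in WT and neither KO. Only the KO lists were cut there, which raises the number in WT alone. With regions at or above the median count the order turned, 1751 against 1721. The same simulation placed 3065 regions (2971 to 3161) in both KO lists and not WT. On autosomes alone, 3135 regions were observed against 2849 (2753 to 2945) in the simulation. The level for independent lists, lowered by WT regions in its total, was 3529, and 3120 on autosomes. The 2 male lists without the female KO list shared 2033 regions on autosomes against 1760 (1683 to 1843), and female KO and WT without male KO 1123 against 1682 (1601 to 1765). The total of the 3 pairs is fixed in the simulation, so a low number in 1 pair raises the others. Depth-scaled lists left 890 regions in both KO lists and not WT and 8589 in WT and neither KO. There too the WT list stays whole and only the KO lists lose regions, which raises the number in WT alone. Chromosome 4 held 8.52% of the regions in both KO lists and not WT and 0.275% of those in WT alone, against 4.93% of all merged regions.

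The longest H3K27me3 region in both KO lists and not WT spanned 148 kb on chromosome 9, from 55142001 to 55289600, with 147.6 kb covered in the female KO list and 100.4 kb in the male KO list. A region on chromosome 4 from 153772801 to 153912000 was covered over 138.6 and 89 kb. In the other 3, on chromosome X from 96308201 to 96454400, chromosome 6 from 30463601 to 30600800 and chromosome 12 from 106026401 to 106155200, the male KO list covered 6.8, 15.8 and 19.2 kb of spans of 146, 137 and 129 kb. The region on chromosome 12 carried H3K27ac over 65.4 kb in WT, 32.6 kb in the male KO line and 6.4 kb in the female KO line. The longest WT region without H3K27me3 in the KO lists was 34.6 kb, on chromosome 5 from 135907601 to 135942200, at 14.2 reads per kb. The next 4 were on chromosome 10 from 86346401 to 86361000, chromosome 5 from 68459601 to 68471400, chromosome 19 from 52985001 to 52996800 and chromosome 10 from 39252001 to 39263400. None of the 5 overlapped H3K4me3 or H3K27ac regions in any line.

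**Figure D2:**
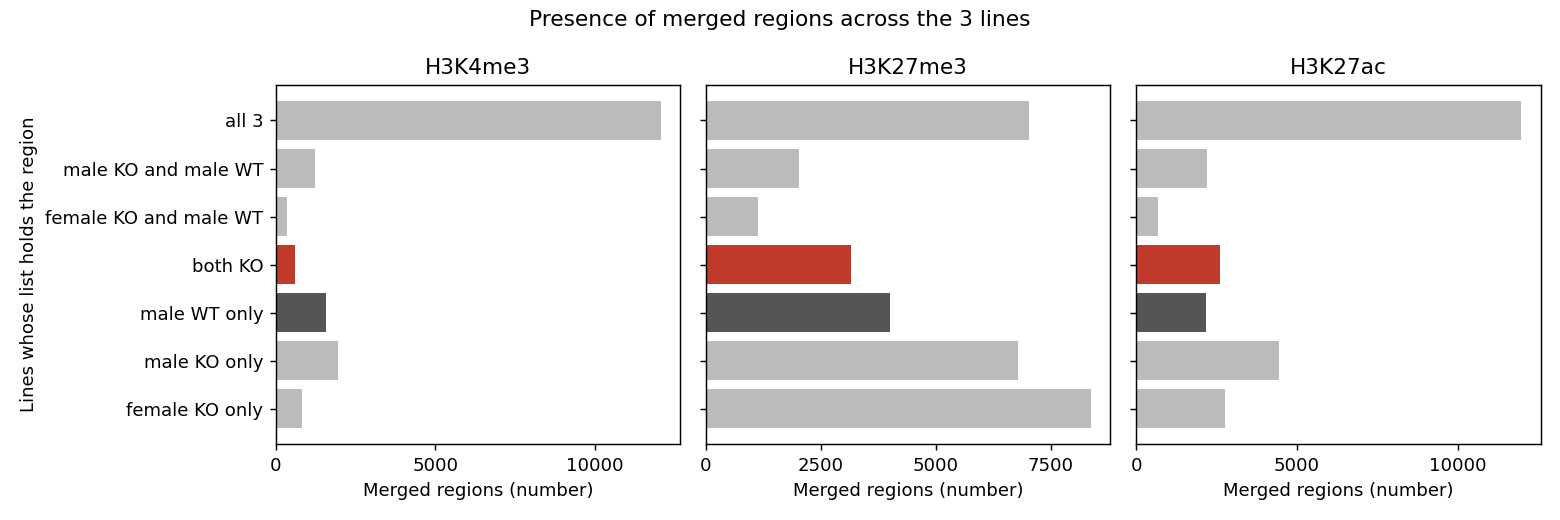
Number of merged regions by the lines whose lists hold them, for H3K4me3, H3K27me3 and H3K27ac, with regions in both KO lists and not WT in red and regions in WT alone in dark grey. Regions in all 3 lists number 12061 for H3K4me3, 7027 for H3K27me3 and 11972 for H3K27ac.

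For H3K27ac, a WT region overlapped 67.3% of the male KO regions (66.7 to 67.8%), and a male KO region overlapped 83.5% of the WT regions (83.0 to 84.0%). The Jaccard index was 0.516 for male KO and WT, against 0.0268 for shifted lists, 0.496 between the KO lines and 0.401 between female KO and WT. Of 26835 merged regions, 11972 were in all 3 lists, 2600 in both KO lists and not WT, and 2178 in WT and neither KO. The simulation placed 2409 regions (2313 to 2503) in both KO lists and not WT. The level for independent lists, lowered by WT regions in its total, was 1404, so no excess over it can be read. The 2 male lists without the female KO list shared 2207 regions against 1900 (1814 to 1988), and female KO and WT without male KO 688 against 1186 (1115 to 1254). H3K4me3 of any line overlapped 47.2% of the regions in both KO lists and not WT (45.2 to 49.1%), 30.1% of those in male KO and WT and 30.1% of those in female KO and WT, without the third list, and 79.4% of those in all 3 lists (78.7 to 80.1%). Of the regions in 1 list alone it overlapped 12.9% for WT (11.6 to 14.4%), 22.8% for male KO and 21.7% for female KO. Median widths differed too, 6 kb for both KO lists and not WT against 2.8 kb for WT alone. When a list was counted only if it covered at least 50% of the merged region, 4940 regions counted as in both KO lists and not WT, and 2397 as in WT alone. These can hold WT regions that cover less than 50% of them, so the rise from 2600 does not show more regions absent from WT. The order turned with depth-scaled lists, 2280 in both KO lists and not WT against 2795 in WT alone. The WT list stays whole in that scaling and only the KO lists lose regions, which raises the number in WT alone. With lists of the same covered length the numbers were 123 and 7555, but only the KO lists were cut there, which raises the number in WT alone.

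The longest H3K27ac region in both KO lists and not WT lay on chromosome 6 from 120025601 to 120077800, with 3375 reads over 52.2 kb in the female KO list and 766 reads over 12.6 kb in the male KO list. On chromosome 4 from 119795401 to 119847000 the order was the other way, with 388 reads in the female KO list and 3209 in the male KO list. The region on chromosome 6 from 146873601 to 146923200 held 3838 and 2689 reads over 49.6 and 38.8 kb. The other 2 were on chromosome 19 from 43566601 to 43618000 and chromosome 4 from 43333401 to 43384400. Of the 5 longest WT regions without H3K27ac in the KO lists, 3 overlapped H3K27me3 of the female KO line, on chromosome 1 from 132714001 to 132732600, chromosome 8 from 73241001 to 73257800 and chromosome 1 from 75005201 to 75020600. H3K27me3 of the male KO line covered 13.2 kb of the region on chromosome 8. The regions on chromosome 10 from 51885201 to 51901800 and chromosome 7 from 114821801 to 114836400 carried no H3K27me3 in any line.

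Combinations of marks at H3K4me3 regions, used in place of promoters, were compared because loss of an H3K27 demethylase bears on H3K27me3 there. H3K27me3 overlapped 29.7% of the H3K4me3 regions in the female KO line (29.0 to 30.5%), 19.2% in the male KO line (18.6 to 19.8%) and 8.97% in WT (8.54 to 9.42%). H3K27ac overlapped 82.8, 77.5 and 74.8%. Both H3K27me3 and H3K27ac were present at 19.5% of H3K4me3 regions in the female KO line, 7.16% in the male KO line and 2.17% in WT. These shares use each line's own H3K4me3 list. The H3K27me3 lists covered 13.0, 8.96 and 5.45% of the genome in the female KO, male KO and WT lines. A longer list meets more H3K4me3 regions by placement alone, and no level for shifted lists was computed here. The order of the shares is therefore not shown to be particular to H3K4me3 regions. At the 12061 H3K4me3 regions held by all 3 lines, H3K27me3 overlapped 30.5% in female KO, 13.9% in male KO and 9.79% in WT. H3K27me3 without H3K27ac was at 8.81, 4.60 and 6.62% of them. For this state the male KO line was below WT there, but above it with each line's own list. Of the 12061 regions, 8891 carried only H3K27ac in WT. Of these 8891, 93.9% (93.4 to 94.4%) kept that state in the male KO line and 78.3% (77.5 to 79.2%) in the female KO line. A further 4.49% in the male KO line and 19.2% in the female KO line carried both H3K27me3 and H3K27ac. Of the 799 regions with only H3K27me3 in WT, 13.0% (10.9 to 15.5%) carried only H3K27ac in the male KO line and 4.51% (3.27 to 6.17%) in the female KO line. A further 38.2% in the male KO line and 26.4% in the female KO line carried both marks. Of the 1989 regions with neither mark in WT, 51.3 and 41.1% carried only H3K27ac in the male and female KO lines. With depth-scaled lists the share of H3K4me3 regions with H3K27me3 was 15.1% in the female KO line, 17.7% in the male KO line and 8.98% in WT, so the KO lines changed order.

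An exchange of H3K27ac for H3K27me3 was looked for at the 20324 H3K27ac regions of WT. In the male KO line, 223 of the 3354 WT regions without H3K27ac overlapped an H3K27me3 region absent from WT, 6.65% (5.85 to 7.54%), against 393 of the 16970 that kept H3K27ac, 2.32% (2.10 to 2.55%). The WT regions without H3K27ac in the male KO line had a median width of 3.2 kb and those with it 4.4 kb. In the female KO line these were 811 of 4561 regions, 17.8% (16.7 to 18.9%), and 1577 of 15763 (9.55 to 10.5%). Over all WT H3K27ac regions the overlap was 3.03% in the male KO line, below the 4.96% of shifted lists. In the female KO line it was 11.7%, above the 5.93% of shifted lists. Shifted regions could land anywhere on a chromosome, also in WT H3K27me3 regions, where the gained regions cannot lie. The shifted level is therefore not matched to the places open to gained regions. In the reverse direction, 2.64% of the WT H3K27me3 regions lost in the male KO line overlapped an H3K27ac region absent from WT, against 3.02% of those kept. For the female KO line these were 69 of 6876 regions lost (0.794 to 1.27%) and 2.08% of those kept. The difference of -0.380 percentage points in the male KO line took the other sign under 3 alternatives. The difference between lost and kept H3K27ac regions fell from 4.33 to 0.914 percentage points in the male KO line and from 7.78 to 0.691 in the female KO line with lists of the same covered length. With depth-scaled lists it was 3.48 and 0.573.

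Large H3K27ac domains, clusters of the kind called super-enhancers, were stitched from neighbouring regions, and the 500 with the highest summed count were compared. Of the 500 domains of the male KO line, 320 overlapped 1 of the 500 of WT, 64.0% (59.7 to 68.1%), and 334 overlapped 1 of the female KO line. Of the 500 of the female KO line, 276 overlapped those of WT, 55.2% (50.8 to 59.5%). In the male KO line 86 domains were among the 500 of both KO lines and not of WT, and 127 WT domains were among the 500 of neither KO line. Each of the 86 still overlapped an H3K27ac region in WT. The longest of the 86 spanned 278 kb on chromosome 4, from 154430001 to 154708000, with 21490 reads in the male KO line, 8789 in the female KO line and 846 in WT. Scaled to WT by reads per kb in shared bins, a scaling chosen after seeing the data, the KO counts were 9630 and 4890. The second lay on the same chromosome from 154839201 to 155046400, and the others were on chromosome 14 from 8637601 to 8797200, chromosome 2 from 60622601 to 60746000 and chromosome 10 from 12569401 to 12687200. The longest WT domains outside the 500 of both KO lines were on chromosome 1 from 37573001 to 37694000, chromosome 2 from 24259801 to 24379400, chromosome 1 from 64831201 to 64937800, chromosome 9 from 120773601 to 120878800 and chromosome 17 from 35296401 to 35401600. Unscaled counts were above WT in both KO lines for the last 3, such as 3777 and 4342 in the female and male KO lines against 2549 on chromosome 17. After the same scaling both KO lines were below WT in all 5, which the choice of domains outside both KO sets of 500 favours. On chromosome 17 the scaled counts were 2101 and 1946, on chromosome 9 2301 and 1830 against 2490, and on chromosome 1 from 64831201 1526 and 1352 against 2594. In the first domain they were 446 and 1690 against 2670, and on chromosome 2 662 and 833 against 2740. Without H3K27ac regions that overlap H3K4me3, an alternative chosen after seeing the data, 207 male KO and 168 female KO domains overlapped WT domains.

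The X chromosome separated the female line from the male lines in H3K27me3, which is broad on the inactive X of female cells. The female KO list held 1965 H3K27me3 regions on X over 16.0 Mb, 9.60% of the chromosome, against 74 regions over 0.310 Mb in the male KO list and 48 over 0.141 Mb in WT. The X coverage of the female KO line was 113 times that of WT, whereas the median ratio of the autosomes was 2.58. Relative to the autosomes of the same line, X coverage was 0.721 in female KO, 0.0194 in male KO and 0.0145 in WT. X was thus covered less than the autosomes in the female KO line too, and the ratio of 113 rests on the small WT coverage. The X regions of the female KO list had a median width of 5.4 kb, against 8.4 kb over all its H3K27me3 regions. With depth-scaled lists the X coverage of the female KO line was 10.6 times that of WT, over 310 regions, and X held 1.67% of the female KO H3K27me3 length, against 4.63% with all regions. H3K4me3 regions on X numbered 482, 545 and 506 and H3K27ac regions 529, 633 and 577 in the female KO, male KO and WT lists. On Y the female KO lists held 0 regions. The male KO lists held 5 H3K4me3, 5 H3K27me3 and 10 H3K27ac regions there, and the WT lists 2, 0 and 0. Among autosomes, chromosome 4 had the highest ratio to WT for each mark in both KO lines. For H3K27me3 the ratio was 5.15 in the male KO line, with a median of 1.62 over autosomes, and 9.68 in the female KO line. In shared regions, WT reads per kb on chromosome 4 were also low for each mark. Relative to its autosomes they were 0.774 for H3K4me3, 0.833 for H3K27me3 and 0.832 for H3K27ac. DNA copy number was not measured, so a shift of all 3 marks there cannot be read as a change in chromatin. That bears on the chromosome 4 regions and domains named above too.

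**Figure D3:**
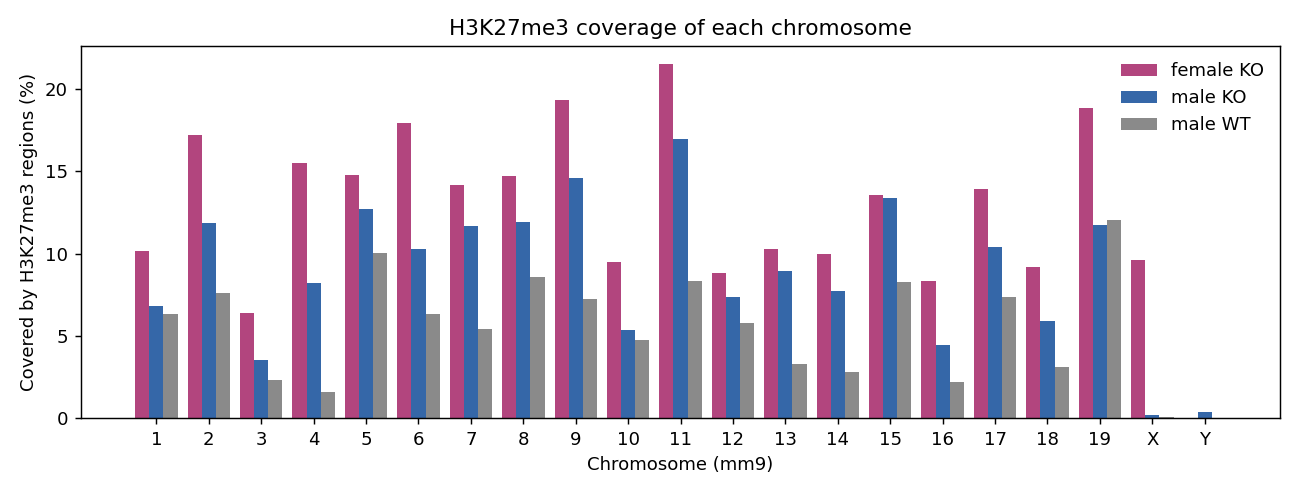
Percent of each mm9 chromosome covered by H3K27me3 regions, with 1 bar per line. Coverage of X is 9.60% in the female KO line, and coverage of chromosome 4 is 15.5% in the female KO line, 8.23% in the male KO line and 1.60% in WT.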

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

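All tests in this part were chosen after the results they bear on had been seen. For the longer coverage in KO lines, 5 forms of the depth comparison were computed, and the rule that number and length had to point the same way at 3 density minimums was set after some of those values were known.

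The KO lines moved in opposite directions from WT in 4 measures. The number of regions, female KO over WT, was 0.880 for H3K4me3, 0.812 for H3K27me3 and 0.910 for H3K27ac, against 1.06, 1.08 and 1.18 for male KO over WT. With depth-scaled lists, where the WT list stays whole, the H3K27me3 number of the male KO line was 0.990 times that of WT. Both KO lines were then below it. The H3K4me3 covered length was 1.13 times that of WT in the female KO line and 0.848 times in the male KO line. These differences between the KO lines were not tested, since each rests on 1 library, and the female comparison also crosses sex.

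A candidate explanation for the lower number of regions in the female KO lists is that neighbouring regions were joined in longer ones. After regions were merged across the 3 lists, the female KO list held 19704 H3K27me3 loci against 14202 in WT, and 18024 H3K27ac loci against 17045. With depth-scaled lists the order turned, to 5909 against 19721 and 16257 against 17971. The WT list stays whole there and only the KO lists lose regions, so that turn cannot decide about joining. Joining was not excluded for these 2 marks. For H3K4me3 the female KO list still held 13832 loci against 15197 in WT, and 13696 against 15178 with depth-scaled lists. That argues against joining as the whole account for that mark. The sex, the line and the loss of Kdm6a stay open there, untested.

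The longer H3K27me3 and H3K27ac coverage of the KO lines could come from more reads, from a change in the cells, or from both. KO-only regions that reached the median WT density after scaling were set against WT-only regions that did. In the male KO line they numbered 1889 against 2214 for H3K27me3 and 529 against 409 for H3K27ac, and in the female KO line 471 against 2007 and 488 against 709. Yet the KO-only H3K27me3 regions covered 11.3 Mb in the male KO line, against 5.72 Mb in WT. In the female KO line lengths also went against the numbers, 11.4 against 5.02 Mb for H3K27me3 and 4.09 against 3.76 Mb for H3K27ac. For H3K27ac in the male KO line the order of lengths turned at the 75th percentile of density (0.531 against 0.576 Mb), so depth and a change in the cells cannot be told apart for either mark or line. Higher H3K27me3 throughout the genome of lines without Kdm6a would also raise the reads in shared regions, which were 3.82 times those of WT in the female KO line and 1.31 times in the male KO line, and without total read numbers or a spike-in this cannot be told apart from depth.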

How the results depend on the processing

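Among the alternatives, the depth-scaled lists, the omission of chromosomes 4, X and Y, the ranking of domains by covered length, the scaled counts of named domains and the domains without H3K4me3 were chosen after seeing the data. Across 36 results, single named domains left aside, 155 alternative values were computed, of which 71 stayed within the bound (1.5 times for a count, the 95% interval for a share or difference), 81 moved outside it and 3 changed sign. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Comparisons at annotated promoters, other promoter windows and gene groups were not run, since no mm9 annotation was used here. Keeping all sequence names moved nothing, because the lists hold no others. Depth limits all of these values: total reads per library are not known. The cause was not tested unless stated.

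Regions at or above the median count keep about 50% of each list by construction, and the lists then held 7031, 8466 and 7996 H3K4me3 regions, 10698, 14245 and 13409 H3K27me3 regions and 9263, 11986 and 10167 H3K27ac regions in the female KO, male KO and WT lines. The shares overlapped (male KO by WT, female KO by male KO, female KO by WT) became 90.0, 95.04 and 93.9% for H3K4me3, 53.7, 58.5 and 46.2% for H3K27me3, and 68.6 and 82.7% for the first pairs of H3K27ac. Regions in both KO lists and not WT fell to 224, 1751 and 1494 for H3K4me3, H3K27me3 and H3K27ac, and those in WT alone to 340, 1721 and 1014. The lost minus kept difference for WT H3K27me3 with gained H3K27ac became 0.810 percentage points in the male KO line, the opposite sign, and -0.105 in the female KO line. The share of H3K27me3 length on X became 2.92, 0.0656 and 0.0568%.

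With an overlap of 50%, the shares in the same order were 82.9, 81.2 and 85.8% for H3K4me3, 36.6, 41.3 and 23.6% for H3K27me3 and 58.9, 62.5 and 42.2% for H3K27ac. H3K4me3 regions with H3K27me3 were 19.5, 16.0 and 6.56% in the female KO, male KO and WT lines. The difference for WT H3K27me3 was 0.931 percentage points in the male KO line, the opposite sign, and -0.211 in the female KO line, and for WT H3K27ac in the female KO line it was 10.1. H3K27ac regions counted as in both KO lists and not WT rose to 4940, which can include regions that WT covers over less than 50%.

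Lists of the same covered length, taken from the highest count down, favour wide regions. The shortest list of a mark stays whole, male KO for H3K4me3 and WT for H3K27me3 and H3K27ac. Regions of the uncut list alone then become more numerous through the cut itself. The shares were 64.2, 99.8 and 98.8% for H3K4me3, 81.4, 85.4 and 88.4% for H3K27me3 and 90.2, 91.9 and 94.2% for H3K27ac. Regions in both KO lists and not WT numbered 80, 92 and 123, and those in WT alone 61, 12555 and 7555. The differences for WT H3K27ac were 0.914 percentage points in the male KO line and 0.691 in the female KO line. Those for WT H3K27me3 were 0.0152, the opposite sign, and -0.277.

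With depth-scaled lists the female KO H3K27me3 list held 6018 regions, 890 regions were in both KO lists and not WT, and 8589 in WT alone. The WT list stays whole in that scaling, so the number in WT alone rises through the scaling itself. H3K4me3 regions with H3K27me3 were 15.1% in the female KO line and 17.7% in the male KO line. The differences for WT H3K27me3 were -0.948 and -2.15 percentage points in the male and female KO lines, and for WT H3K27ac in the female KO line 0.573. The share of H3K27me3 length on X in the female KO line was 1.67%.

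Merging regions closer than 1 kb gave 93.7% of female KO regions overlapped by male KO for H3K4me3 and 83.0% for H3K27ac, and 91.5, 44.3 and 72.3% overlapped by WT for H3K4me3, H3K27me3 and H3K27ac. With 1000 domains, 673 male KO and 612 female KO domains overlapped WT domains, a rise that the larger number sets. Without H3K4me3 regions the numbers were 207 and 168. Counted as a share of the number of regions, X held 9.20, 0.262 and 0.183% of H3K27me3.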

Other observations

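The values in this part were chosen after they had been seen.

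Reads in regions shared by the 3 lines differed between lines on some chromosomes or parts of them. On chromosome 4 the reads per kb of WT relative to its autosomes were 0.774 for H3K4me3, 0.833 for H3K27me3 and 0.832 for H3K27ac, against 0.974, 1.15 and 1.07 in the female KO line and 0.891, 1.02 and 0.919 in the male KO line. On chromosome 15 the male KO line stood at 1.16, 1.26 and 1.16 and WT at 1.07, 1.08 and 1.097. On chromosome 6 the female KO line stood at 1.11, 1.11 and 1.14 and WT at 0.973, 0.955 and 1.02. Over windows of chromosome 4, the log2 ratio of male KO to WT was above 0 in 13 of 26 windows for H3K4me3, 9 of 13 for H3K27me3 and 11 of 21 for H3K27ac, with medians of 0.0016, 0.39 and 0.0032. Over chromosome 15 it was above 0 in 17 of 17, 9 of 14 and 11 of 18 windows, with medians of 0.13, 0.0073 and 0.098. For female KO over WT the medians over chromosome 4 were 0.34, 0.64 and 0.33. These 3 chromosomes were chosen after their values were seen. Within chromosome 4, the windows from 105 to 120 Mb, picked after their values were seen, had a mean log2 ratio of male KO to WT of 0.76 for H3K4me3, 0.93 for H3K27me3 and 0.52 for H3K27ac. From 130 to 145 Mb these were -0.18, 0.04 and -0.10.

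Some H3K27me3 and H3K27ac regions of the male KO line overlapped on the Y chromosome, with similar borders. The H3K27me3 region from 2875601 to 2902600 held 1206 reads, and H3K27ac regions from 2875601 to 2887400, 2888001 to 2896800 and 2897401 to 2902400 held 845, 560 and 256 reads. Overlap of lists does not show that the marks lie together. Whether reads map uniquely there was not checked, and the control library is not known.

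Set apart by list, WT was not the line with the most distinct regions. For H3K27me3, 7159 merged regions separated WT from both KO lists, 7933 separated the male KO line from the others and 10413 the female KO line. For H3K27ac the numbers were 4778, 5114 and 4971, and for H3K4me3 2157, 2279 and 2068. With lists of the same covered length, the line whose list stays whole had the most for each mark. This was WT for H3K27me3 (12647) and H3K27ac (7678), and male KO for H3K4me3 (5814), so the cut can set that order. With regions at or above the median count WT had the most for H3K27ac (2508).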
